A study of Mus musculus with 6 samples.

How the data were processed

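Islet RNA from 3 Mrpp3WT and 3 Mrpp3N434S mice on a high-fat diet was made into Illumina TruSeq small RNA libraries, per the labels' protocols. Such libraries join adapters to short RNA with free ends, so they hold fragments and short transcripts rather than whole tRNAs. An RNA on which reverse transcriptase stops before the 5′ adapter can be lost from the reads. Reads that begin 3′ of such a base can then come from RNA that already ended there. Reads were trimmed and aligned with Trim Galore, cutadapt, FastQC and STAR against GRCm38.p6, per the submitters' processing notes, with versions and order not given. The read length, the tool that counted bases, its base quality filter, its depth limit and the treatment of reads that also match nuclear copies of mitochondrial DNA are not given in the sources used here.

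The deposited values of each library are counts of A, C, G, T and N on each strand at each position of the mitochondrial chromosome, not scaled by the authors, per the file headers. From the values, the depth of both strands together never passed 8000, and 3 mutant libraries reached 7997 to 8000, so a depth limit is inferred that would remove reads at the most abundant positions, all of them in rRNA. A mismatch rate is a ratio within 1 position and is less affected by such a limit than a level. The authors' deposited table of position 9 base counts has 6 blocks whose headings match no sample label, so its 16 columns of per-sample values were not assigned to samples. From it came the position 9 coordinates and base sums over all blocks. The labels name no sequencing batch.

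Genes were the 37 of the mitochondrial chromosome (22 tRNA, 2 rRNA, 13 protein-coding) in the GENCODE annotation of GRCm38, the build named in the submitters' processing notes. Depth was taken on the strand of each gene, so genes that overlap on opposite strands were kept apart; tRNAs that overlap a neighbour by a few bases share depth there. The 6 libraries had a summed base depth from 3156761 to 10923311. No pair of libraries agreed within counting noise: the chi-square per degree of freedom over genes was 3.33 or more for each pair, so all 6 counted as separate samples.

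Position 9 mismatch was the share of bases other than the reference among all bases read on the tRNA strand. For every single-library share, an exact (Clopper-Pearson) 95% binomial interval was computed; at the lowest tested depths it was wide, for example 0.343% to 9.81% for mt-Tc in mutant replicate 3. Such intervals cover counting error only, since amplified reads are not independent molecules. The edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) compared mismatched and reference counts with an effect for each library and a term for the genotype's effect on their ratio, for tRNAs with a depth of at least 50 in every library. The same model compared the depth of the 10 nt upstream (leader) or downstream (trailer) of each tRNA with the mean depth of the tRNA, for flanks with a mean depth of at least 10, and mismatches at other tRNA and rRNA positions with a mean mismatch of at least 5% over all libraries. Mean depth per gene, rounded, was tested with edgeR after TMM scaling over the mitochondrial genes, for genes with a mean of at least 10. Changes are therefore relative to other mitochondrial RNA. Standard errors came from the log2 change and its F statistic.

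Adjusted p-values are Benjamini-Hochberg values within each test, with a threshold of 0.05. List means and class shares were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries. Lists were also tested with fry in limma 3.58.1, which asks whether a list's members move one way on balance and does not compare the list with other genes. The tests, the lists (A9, G9 and C9 or U9 tRNAs, RNA classes, light- and heavy-strand tRNAs, tRNAs beside another tRNA) and the named-gene rule were fixed before the data were examined. The rule named all tRNAs past the threshold and up to 10 by size of the position 9 difference, up to 10 genes past the threshold for depth plus both rRNA genes, up to 8 leaders and 8 trailers past the threshold or else the 4 largest, and the sites of highest mismatch. mt-Ty and mt-Tw at position 9, mt-Th among the leaders, the members of lists counted at 5 or fewer, the coverage of position 9 and the regions outside genes were added after their values were seen.

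Alternatives were limma on log2 odds with 0.5 added to each count, DESeq2 1.42.0, other minimum depths and window lengths, other scalings, no filter, the maximum depth per gene, the replicate number as a block, and leaving out each library in turn. After the data were seen, scaling to the tRNA genes and leaving out positions above a depth of 6000 were added. The models were tested on simulated data with the real depths. Of position 9 ratios changed by 1 on the log2 scale 61% were recovered, and 98% of those changed by 2, over 10 tRNAs. For depth per gene, over 34 genes, 44.4% and 98% were recovered, and for trailers, over 20, 31% and 87%. Of unchanged features 0.333% to 2.5% were called. Figures were drawn with matplotlib 3.10.9.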

Results

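Small RNA was sequenced from pancreatic islets, the hormone-secreting cell clusters of the pancreas, of mice fed a high-fat diet for 14 weeks. The genotypes were Mrpp3WT (wild type, 3 libraries) and Mrpp3N434S (mutant, 3 libraries), and the design text gives 3 mice of each genotype. MRPP3 is the nuclease subunit of mitochondrial RNase P, the enzyme that frees the 5′ ends of mitochondrial tRNAs from long precursor transcripts. The same complex contains MRPP1, which methylates the purine at position 9 of mitochondrial tRNAs, and reverse transcriptase can misread or stop at such a methylated base. The series asks whether small RNA coverage and the mismatch rate at position 9 differ between the genotypes. The values analysed were counts of each base at every position of the mitochondrial chromosome (chrM, 16299 positions, GRCm38), separately for each strand.

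The summed base depth was 4337052, 3464994 and 3156761 in wild-type replicates 1, 2 and 3, and 10923311, 5461367 and 5928569 in mutant replicates 1, 2 and 3. All mutant libraries were therefore deeper than all wild-type libraries. The extra depth lay on the forward strand, which held 2764211 to 3747204 bases in the wild type and 5026986 to 10302401 in the mutant. Reverse-strand depth overlapped, at 392550 to 589848 and 434381 to 620910 bases. No position exceeded a depth of 8000 over both strands in any library, and positions above 6000 numbered 90 to 98 per library except for 408 in mutant replicate 1, all within the 2 rRNA genes. The highest depth was 7436 to 7756 in the wild-type libraries and 7997 to 8000 in the mutant ones. A limit at 8000 is inferred from these values, and levels of the most abundant rRNA fragments may be lower limits, above all in the mutant. The nuclear gene Mrpp3 lies outside these counts, so the genotype of each library was not checked.

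Among the tRNAs with a depth of at least 50 at position 9 in every library, mismatch was higher in those with adenosine there than in the others, in both genotypes. Below that depth this did not hold throughout: the G9 tRNA mt-Ty (depth 23 to 55) averaged 14.0% ± 2.64 in the wild type and 22.4% ± 7.82 in the mutant (SD, n = 3), and the A9 tRNA mt-Tw (depth 7 to 14) had 0% in both. In the wild type the mismatched share was 74.5% ± 3.53 (SD, n = 3) in the asparagine tRNA mt-Tn, 47.6% ± 1.92 in the histidine tRNA mt-Th, 38.1% ± 1.18 in the valine tRNA mt-Tv, 19.9% ± 1.66 in the alanine tRNA mt-Ta and 12.0% ± 1.01 in the glutamate tRNA mt-Te. The mutant values were 73.1% ± 4.36, 43.3% ± 12.7, 34.8% ± 3.72, 15.7% ± 2.94 and 7.46% ± 2.25 (SD, n = 3), each below the wild-type mean. The G9 tRNAs mt-Tq (glutamine) and mt-Tc (cysteine) had 1.29% ± 0.325 and 1.62% ± 0.820 in the wild type against 1.13% ± 0.424 and 3.09% ± 0.740 in the mutant. The C9 tRNAs mt-Tm (methionine) and mt-Ts1 (serine) and the U9 tRNA mt-Ts2 (serine), which carry no methylatable purine there, stayed at or below 0.418% in both group means.

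No tRNA passed the test for a changed position 9 mismatch. Of the 22 mitochondrial tRNAs, 10 had a depth of at least 50 at the position in every library. Among these, edgeR's quasi-likelihood test gave 0 at an adjusted p of 0.05, 2 at an unadjusted p under 0.05, and the same 0 after adjustment by limma and by DESeq2, which had 1 and 0 at an unadjusted p under 0.05. The pair with the smallest p-values comprised mt-Te and mt-Ts2. In mt-Te (chrM 14071 to 14139, reverse strand, position 9 at 14131) the log2 odds of a mismatch differed by -0.71 (SE 0.32, 95% interval -1.36 to -0.06, adjusted p = 0.17 by edgeR), and each mutant library (9.21%, 8.24% and 4.92%) lay below each wild-type library (12.7%, 10.8% and 12.4%). In mt-Ts2 (position 9 at 11621, forward strand) the mismatch was 0.164% ± 0.0979 in the wild type and 0.380% ± 0.121 in the mutant (SD, n = 3; log2 odds 1.22, SE 0.55, edgeR adjusted p = 0.17). There, and in mt-Tc, the libraries separated as fully in the opposite direction, each mutant library above each wild-type one (exact permutation p = 0.1 in all 3 tRNAs, the smallest possible). For the other 8 tRNAs the edgeR adjusted p was 0.344 to 0.738. The 95% intervals of the log2 odds difference ran from -0.65 to 0.44 for mt-Tn (position 5151), from -0.82 to 0.40 for mt-Tv (1033), from -0.98 to 0.14 for mt-Ta (5078) and from -0.87 to 0.36 for mt-Th (11553). They reached from 0.00 to 2.36 for mt-Tc (5249), from -1.11 to 0.70 for mt-Tq (3834), from -1.16 to 2.63 for mt-Tm (3853) and from -2.27 to 3.42 for mt-Ts1 (6930). The edgeR unadjusted p of mt-Tc was 0.112, so its interval, which ends at 0.00, is narrower than that test implies. In mt-Th, mutant replicate 3 had 28.8% against 52.7% and 48.3% in mutant replicates 1 and 2, and the log2 odds difference of -0.26 became 0.20 without that library.

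**Figure D1:**
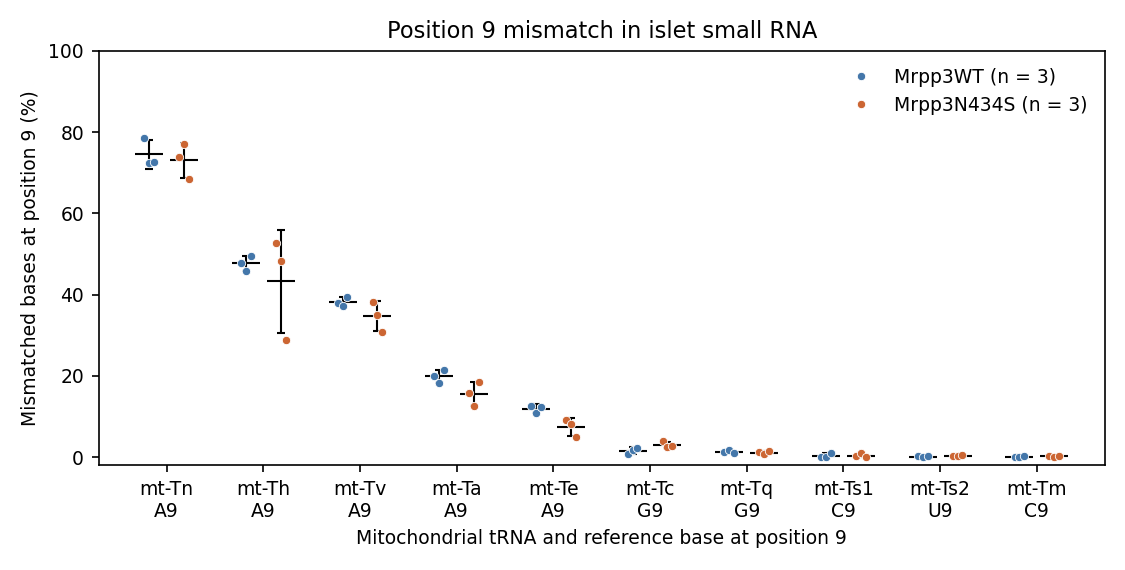
Percent of bases at position 9 that differ from the reference, for the 10 mitochondrial tRNAs with a depth of at least 50 in every library. Points are single libraries and black bars the mean ± SD of 3 libraries per genotype; the A9 tRNAs range from 12.0% to 74.5% in the wild-type mean, and no tRNA passed the test between genotypes.

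By list, the 5 testable A9 tRNAs averaged 38.4% ± 1.41 in the wild type and 34.9% ± 4.03 in the mutant (SD, n = 3), a difference of -3.57 points, with all 5 lower in the mutant mean. An exact two-sided permutation test gave p = 0.2 (adjusted over the 3 lists, 0.45), where the smallest p that 3 against 3 libraries allow is 0.1. Without mutant replicate 3 the difference was -1.30 points. The 2 testable G9 tRNAs averaged 1.46% ± 0.443 and 2.11% ± 0.478 (exact permutation p = 0.3), and the 3 C9 or U9 tRNAs 0.205% ± 0.257 and 0.326% ± 0.105 (exact permutation p = 0.5). Leaving out a library moved the C9 or U9 difference of 0.121 points from 0.0273 (without wild-type replicate 2) to 0.268 (without wild-type replicate 3). No tRNA passed in any of these lists when adjusted over the list alone, the same 0 as over all 10. The limma rotation test fry gave adjusted p = 0.368, 0.459 and 0.368 for the A9, G9 and C9 or U9 lists. Across the other tRNA positions (784 sites) the mean mismatch per library was 0.360%, 0.381% and 0.368% in the wild type and 0.321%, 0.339% and 0.357% in the mutant, and the median was 0.174% to 0.223% and 0.161% to 0.217%.

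The kind of mismatch differed between tRNAs. Counting positions from 1 at the 5′ end of the tRNA, and over all 6 libraries together, A9U made up 93.5% of the mismatched bases in mt-Te, 71.7% in mt-Tv and 68.6% in mt-Th, whereas A9G made up 80.9% in mt-Tn and 54.4% in mt-Ta. The listed position 9 of mt-Th is base 8 of its annotated gene, and in the other 21 tRNAs it is base 9. The base sums of the authors' deposited table of position 9 counts, taken over all of its columns, were identical to the sums over the 6 libraries for all 22 tRNAs.

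Of the 22 tRNAs, 12 had too few reads over position 9 to be tested, and for some of them the rest of the tRNA was well covered. As a measure added after the data were seen, the depth at position 9 was divided by the highest depth over bases 20 to 60 of the same tRNA, for the 13 tRNAs in which that depth was at least 50 in every library. This share averaged 98.4% in mt-Ts2, 98.1% in mt-Ts1 and 94.4% in mt-Tm over the 6 libraries. It was 84.9% in mt-Tq, 34.7% in mt-Te, 5.75% in the glycine tRNA mt-Tg and 2.11% in the leucine tRNA mt-Tl1. The gene of mt-Ts2 is 59 nt long, so base 60 lies outside it. No tRNA passed the test between genotypes (0 of 13 by edgeR after adjustment, 5 at an unadjusted p under 0.05, all lower in the mutant). The smallest adjusted p was 0.0574, in mt-Tq (89.5% ± 1.24 in the wild type, 80.2% ± 4.69 in the mutant, SD, n = 3) and in mt-Tc (47.5% ± 6.23 and 31.6% ± 5.08).

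**Figure D2:**
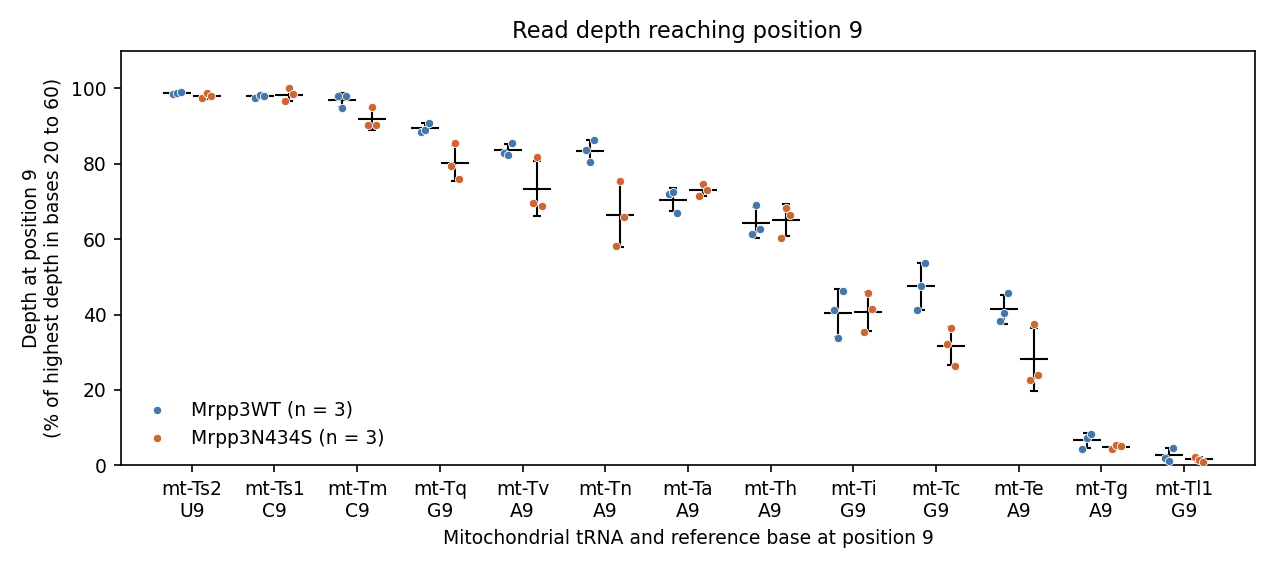
Depth at position 9 as a percent of the highest depth over bases 20 to 60 of the same tRNA, for 13 mitochondrial tRNAs labelled with their reference base at position 9. Points are single libraries and black bars the mean ± SD of 3 libraries per genotype; the means over all libraries range from 2.11% in mt-Tl1 to 98.4% in mt-Ts2.

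Relative to the other mitochondrial RNA, fragments of the small ribosomal RNA rose and the methionine tRNA fell in the mutant. mt-Rnr1 (small rRNA, chrM 70 to 1024, forward strand) had a normalized depth of 735 ± 62.3 in the wild type and 1370 ± 299 in the mutant (SD, n = 3), a 1.87-fold increase (log2 0.90, SE 0.25, edgeR adjusted p = 0.0124). mt-Tm (chrM 3845 to 3913, forward strand) went from 1450 ± 320 to 777 ± 105, which is 1.87-fold lower (log2 -0.90, SE 0.25, edgeR adjusted p = 0.0124). Both differences held in every library, each mutant value lying beyond each wild-type value. mt-Rnr2 (large rRNA, chrM 1094 to 2675), whose 5′ end held positions above a depth of 6000 in all libraries, measured 1450 ± 183 and 2060 ± 261 (log2 0.51, SE 0.24, edgeR adjusted p = 0.117). It passed with the positions above 6000 left out (log2 0.83, edgeR adjusted p = 0.0237) and scaled to tRNA (log2 0.89, edgeR adjusted p = 0.0108). The sign reversed by maximum depth per gene (log2 -0.36) and scaled to rRNA (log2 -0.14). The inferred limit of 8000 bounds the maximum depth, and the rRNA scale contains mt-Rnr2 itself, so neither reversal shows its direction.

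Of the 37 mitochondrial genes, 34 had a mean depth of at least 10, and 2 changed (1 higher, 1 lower) by edgeR with TMM scaling. The calls depended on the scaling, since the groups differed in how much depth the rRNA took. Scaling by library totals gave 5 (4 higher, 1 lower), by the summed rRNA genes 16 (0 higher, 16 lower) and by the summed tRNA genes 12 (12 higher, 0 lower). These scalings shifted the median of all genes by 0.11, -0.66 and 0.41 on the log2 scale. mt-Tm measured -0.50 scaled to tRNA, where it lost its call (edgeR adjusted p = 0.0932), and -1.57 scaled to rRNA. mt-Rnr1 measured 1.29 scaled to tRNA and 0.24 scaled to rRNA, where it lost its call (edgeR adjusted p = 0.106). The tRNA scale contains mt-Tm and the rRNA scale contains mt-Rnr1, so each takes out part of that gene's own change. Without wild-type replicate 1, and likewise without wild-type replicate 3, 0 genes passed, and the adjusted p of both mt-Rnr1 and mt-Tm was 0.164 and 0.107. Their log2 folds stayed close to the full ones, at 0.84 and 0.82 for mt-Rnr1 and -0.80 and -0.85 for mt-Tm.

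By class, 16 of the 19 testable tRNA genes were lower and 3 (mt-Tl1, mt-Tw and mt-Tp) higher in the mutant, with a median log2 fold of -0.27. The list as a whole did not pass (fry, adjusted p = 0.0886), and its median was -0.15, -0.95 and 0.14 when scaled to totals, rRNA or tRNA. The tRNA scale takes out the summed tRNA change, so a tRNA median on that scale does not show the direction of the change. One tRNA gene, mt-Tm, changed, and 1 also did when adjusted over the list alone. Among the heavy-strand tRNAs 1 of 11 changed over all genes and 3 (mt-Tv, mt-Tm and mt-Tr, all lower) adjusted over the list alone, with a median of -0.26 (fry, adjusted p = 0.0893) that became -0.13 without mutant replicate 1 and 0.16 scaled to tRNA. Among the 8 light-strand tRNAs 0 changed in either way, with a median of -0.34 (fry, adjusted p = 0.296) that became 0.07 scaled to tRNA. Without mutant replicate 1 it was -0.54 and 4 of them passed. Of the rRNA genes 1 changed over all genes and 2 adjusted over the list alone (fry, adjusted p = 0.0761). Of the 13 protein-coding genes 11 were higher in the mutant, with a median of 0.42 that became -0.28 when scaled to rRNA and 0.17 without mutant replicate 1. None changed by edgeR over all genes or adjusted over the list alone (fry, adjusted p = 0.0886). DESeq2 called 2 of the 34 genes, with the same direction split.

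**Figure D3:**
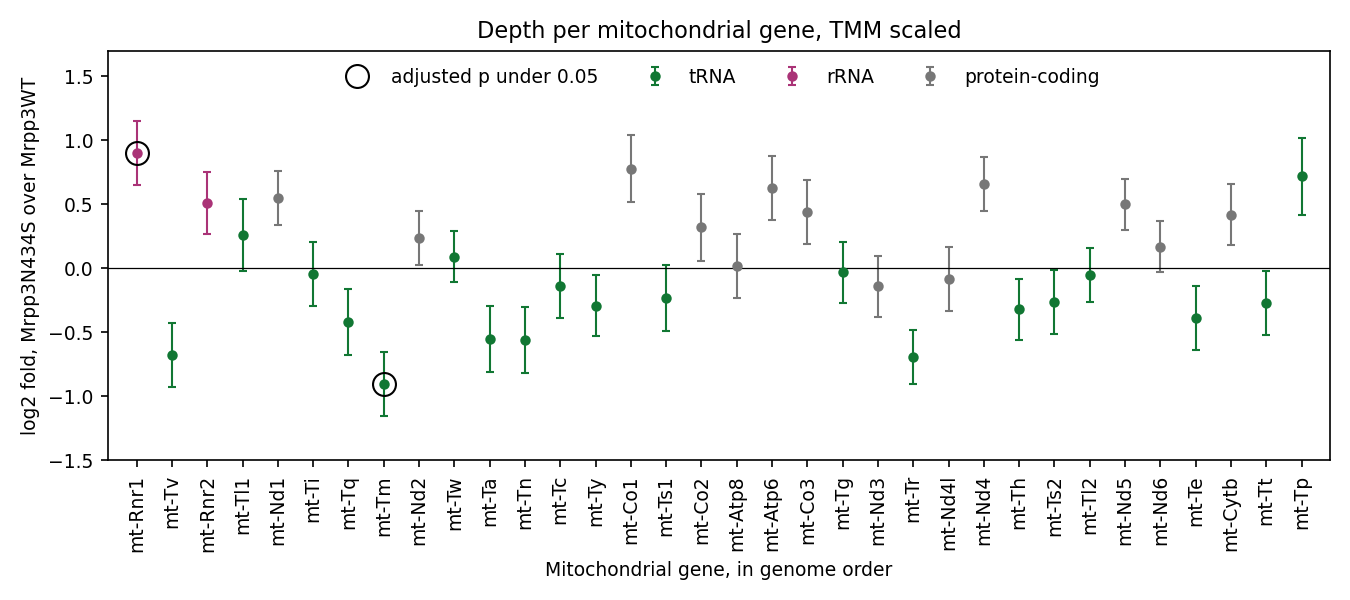
Log2 fold in depth, mutant over wild type, for the 34 mitochondrial genes with a mean depth of at least 10, in genome order and coloured by RNA class. Bars are the standard error of the edgeR fit with TMM scaling. Rings mark the 2 genes with an edgeR adjusted p under 0.05, mt-Rnr1 at 0.90 and mt-Tm at -0.90. The sign of the tRNA median reversed when scaled to tRNA, a scale that takes out the summed tRNA change. The sign of the protein-coding median reversed when scaled to rRNA.

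As shares of all mitochondrial base depth, rRNA took 67.4% ± 2.75 in the wild type and 78.2% ± 1.75 in the mutant (SD, n = 3). tRNA took 13.7% ± 2.40 and 7.88% ± 0.919, and positions or strands outside every annotated gene took 10.5% ± 0.492 and 5.42% ± 1.65. Protein-coding genes took 8.37% ± 0.369 and 8.49% ± 0.819. In the first 3 classes the genotypes did not overlap in any library, which gives the smallest p that the exact two-sided permutation test allows (p = 0.1, adjusted over the 4 classes 0.133), so none could pass. For protein-coding genes the exact permutation p was 1. With the positions above 6000 left out, the rRNA share was 51.8% ± 2.22 and 68.4% ± 3.58 and the tRNA share 20.3% ± 2.62 and 11.4% ± 1.67 (SD, n = 3).

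**Figure D4:**
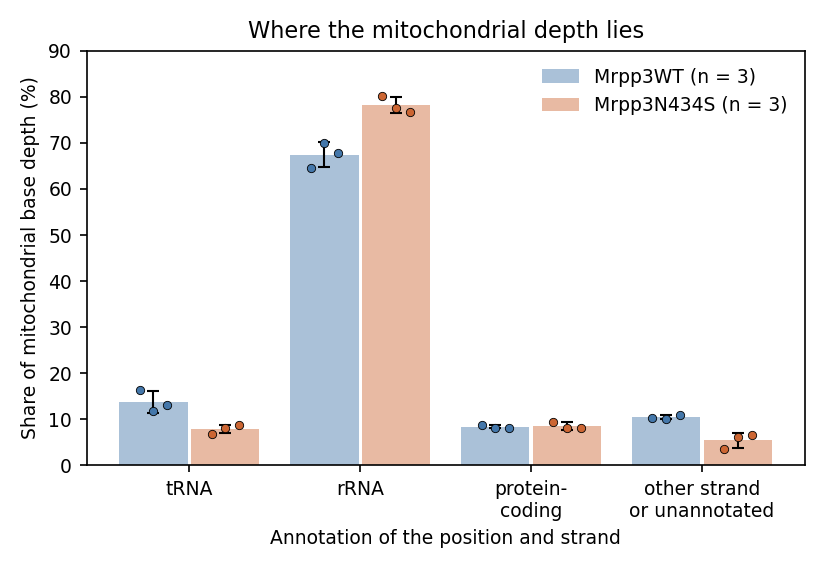
Percent of the mitochondrial base depth on positions and strands annotated as tRNA, rRNA or protein-coding, or outside every annotated gene. Bars are means, error bars the SD and points the 3 libraries of each genotype; rRNA averages 67.4% in the wild type and 78.2% in the mutant, and tRNA 13.7% and 7.88%.

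RNase P cuts the 5′ side of mitochondrial tRNAs, and uncut leaders would add depth directly upstream. Depth there also comes from neighbouring RNA, and reads across the junction were not counted. The leader of mt-Tv, for example, is the end of mt-Rnr1, and that of mt-Tm lies mostly opposite mt-Tq. The ratio therefore cannot tell a change in 5′ cutting from a change in the neighbouring RNA. No tRNA had a changed ratio of leader depth (10 nt upstream) to tRNA depth. The largest differences were in mt-Ty (tyrosine), with a ratio of 0.719 ± 0.344 in the wild type and 0.437 ± 0.257 in the mutant (SD, n = 3; log2 -0.70, SE 0.56), and in mt-Tv, with 0.0973 ± 0.0182 and 0.147 ± 0.0452 (log2 0.58, SE 0.27). Next came mt-Td (aspartate; log2 0.42, SE 1.21) and mt-Tl2 (leucine; log2 -0.20, SE 0.31). Leaving out a library moved mt-Ty from -1.02 to -0.28. The leader of mt-Tl2 lies inside the neighbouring mt-Ts2. Among the steadiest, the leader of mt-Th held 0.0763 ± 0.00175 of the tRNA depth in the wild type and 0.0767 ± 0.00563 in the mutant (log2 0.00, SE 0.20).

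Of the 11 leaders with a mean depth of at least 10, 0 passed by edgeR, and 0 had an unadjusted p under 0.05. limma and DESeq2 also gave 0 by both measures. The smallest edgeR adjusted p was 0.622, in mt-Tv, and the other 10 had 0.999. The 4 leaders inside or touching another tRNA had a median log2 change of -0.12, and the 7 beside an mRNA, an rRNA or an unannotated strand had 0.00. Adjusted over the list alone, 0 passed in either list, and likewise 0 of 3 light-strand and 0 of 8 heavy-strand tRNAs. In simulated data a log2 change of 1 was recovered for 23% of changed leaders and a change of 2 for 93%, so most changes of the smaller size were not detectable at this depth.

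The 3′ ends, which the nuclease ELAC2 cuts, served as the comparison side. RNA directly 3′ of the tryptophan tRNA mt-Tw and the isoleucine tRNA mt-Ti fell in the mutant relative to the tRNA itself. After mt-Tw (chrM 4950 to 5016, forward strand) the ratio of trailer depth (5017 to 5026) to tRNA depth was 41.2 ± 10.3 in the wild type and 14.5 ± 5.89 in the mutant (SD, n = 3; 2.98-fold lower, log2 -1.58, SE 0.41, edgeR adjusted p = 0.0147). After mt-Ti (chrM 3706 to 3774, forward strand) it was 1.33 ± 0.299 and 0.638 ± 0.0988 (2.06-fold lower, log2 -1.04, SE 0.32, edgeR adjusted p = 0.0329). Mean depth in the trailer windows was 450 ± 106 and 245 ± 88.1 for mt-Tw and 132 ± 22.9 and 92.3 ± 4.73 for mt-Ti. The depth of mt-Tw itself, on which its ratio rests, was low. It was 15, 8 and 11 in wild-type replicates 1, 2 and 3 and 20, 12 and 22 in mutant replicates 1, 2 and 3. The RNA after mt-Tw began at its 3′ end and lay on the strand opposite mt-Ta and mt-Tn. The RNA after mt-Ti lay opposite mt-Tq.

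Both were lower in 3 of 3 mutant libraries than in every wild-type library, and they were the 2 changed of 20 testable trailers (0 higher, 2 lower). limma called 1 of them, mt-Tw, and DESeq2 called 0 (adjusted p = 0.0536 for mt-Tw and 0.0691 for mt-Ti). The log2 changes by DESeq2 were equal to those by edgeR, at -1.58 and -1.04. Without wild-type replicate 2, and without wild-type replicate 3, 0 passed, at log2 changes of -1.53 and -1.40 for mt-Tw and -1.07 and -0.87 for mt-Ti. By list, 2 of the 16 trailers beside an mRNA, an rRNA or an unannotated strand changed, and 2 adjusted over the list alone, with a median log2 change of -0.38. Of the 4 touching another tRNA 0 changed in either way, with a median of 0.02. The 2 also made up the changed trailers among 14 heavy-strand tRNAs (2 adjusted over the list alone), and 0 of 6 light-strand tRNAs changed in either way.

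**Figure D5:**
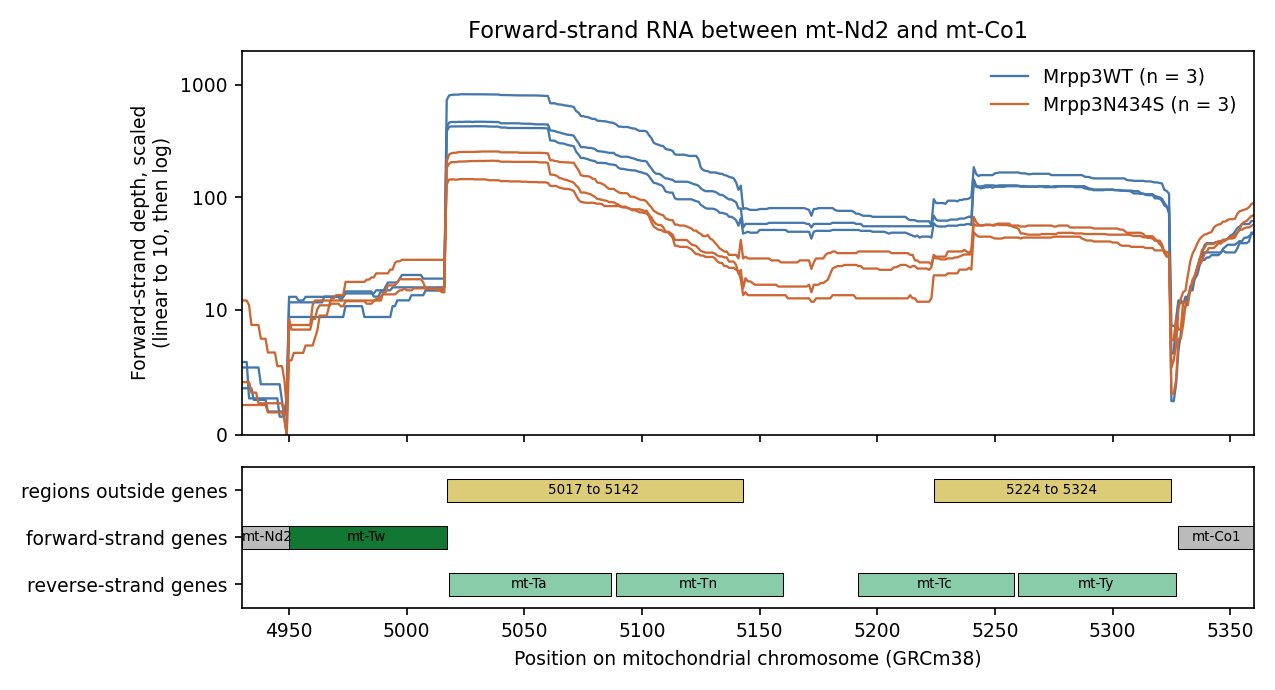
Depth of forward-strand RNA from position 4930 to 5360 of chrM, scaled by TMM factors, with 1 line per library, on an axis that is linear up to 10 and logarithmic above. The lower panel maps the annotated genes by strand and the regions of forward-strand RNA outside genes; from 5017, directly after mt-Tw, to 5324 the 3 mutant lines lie below the 3 wild-type lines, and beyond 5324 they do not.

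Elsewhere in mitochondrial tRNA and rRNA, 1 site had a mean mismatch of at least 5%. It was position 2743 of the leucine tRNA mt-Tl1 (chrM 2676 to 2750, forward strand), where the substitution C68A, counted from the 5′ end of the gene, made up 99.5% of the mismatched bases. The mismatch was 29.9% ± 5.80 in the wild type and 21.9% ± 3.64 in the mutant (SD, n = 3; log2 odds -0.62, SE 0.29, exact permutation p = 0.1). Leaving out a library moved the log2 odds from -0.78 to -0.38, the latter without wild-type replicate 1. That site was the single one of 3297 with a depth of at least 50 in every library to reach 5%, and 35 reached 1%. At 5%, 0 changed by edgeR (0 at an unadjusted p under 0.05), and at 1%, 0 changed and 2 had an unadjusted p under 0.05. After it, the highest means were 3.04% at base 23 of mt-Te (position 14117), 3.01% at base 39 of mt-Ti (3744), 2.82% at base 20 of mt-Th (11565) and 2.65% at base 33 of mt-Th (11578). The adjusted p at these 4 sites was 0.660 to 0.989 by edgeR.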

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

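Leaving out positions above a depth of 6000, scaling to the tRNA genes and every value for regions outside genes were chosen after the data were seen. The 0 calls for position 9 mismatch, leaders and other sites held in all alternatives run, as did the signs of the A9 and the C9 or U9 lists and of the tRNA, rRNA and unannotated shares. The number of genes with changed depth, 2, became 5 by library totals and 6 with no filter. It was 4 by maximum depth per gene and 4 without positions above 6000. It became 16 scaled to rRNA, which takes out the summed rRNA change, and 12 scaled to tRNA, which takes out the summed tRNA change. It ranged from 0 (without wild-type replicate 1 or 3) to 11 (without mutant replicate 3), with 7 without wild-type replicate 2 and 6 without mutant replicate 1 or 2. mt-Rnr2, 0.51 and not past the threshold, measured -0.14 scaled to rRNA and -0.36 by maximum depth. The rRNA scale contains mt-Rnr2 and the inferred depth limit bounds its maximum, so neither value shows its direction. mt-Rnr2 passed at 0.61 with no filter, 0.83 without positions above 6000 and 0.89 scaled to tRNA. mt-Tm, -0.90, lost its call at -0.50 scaled to tRNA and measured -1.57 scaled to rRNA, where mt-Rnr1, 0.90, lost its call at 0.24. Each lost its call on a scale that contains it. The 2 changed trailers became 1 by limma and 0 by DESeq2, and 0 to 2 when leaving out a library (0 without wild-type replicate 2 or 3, 1 without wild-type replicate 1 or mutant replicate 1 or 2). Where both lost their calls without a library, the log2 changes stayed at -1.53 and -1.40 for mt-Tw and -1.07 and -0.87 for mt-Ti. The G9 list mean difference of 0.655 points was -0.0258 weighted by reads, -0.163 at a minimum depth of 200, which leaves mt-Tq alone, and 2.19 at 20. Leaving out a library moved mt-Tq from -0.33 to 0.03, mt-Tn from -0.24 to 0.07, mt-Ts1 from -0.34 to 0.96 and mt-Th from -0.55 to 0.20 at position 9, and the leaders of mt-Ty from -1.02 to -0.28, mt-Td from -0.42 to 1.09 and mt-Tl2 from -0.41 to 0.09. The protein-coding share difference of 0.126 points was -0.374 within annotated genes, -0.130 without positions above 6000 and -0.347 to 0.365 without a library. The region from 12924 to 12997 measured 0.13 scaled to tRNA. The replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.02, -0.23 and 0.25 in depth and 0.23, 0.01 and -0.05 at position 9, and 2 and 0 of 6 libraries correlated best with their own number. With the number as a block, 0 genes changed in depth and 2 trailers did. mt-Rnr1 and mt-Tm then had an edgeR adjusted p of 0.0719, at log2 folds of 0.88 and -0.89. Elsewhere the cause was not tested. For other sites, limma, DESeq2 and a minimum depth of 200 were not run, since 1 site or none was left, and mt-Ts1 gave no finite value for its most frequent mismatch alone or without wild-type replicate 3, which its range leaves out.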

Other observations

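The coverage of position 9, the regions outside genes and the tests of explanations for them and for mt-Rnr1 were chosen after the results were seen; the counts over other splits were planned. RNA outside annotated genes formed 8 regions of at least 8 nt with a mean depth of at least 40, picked without regard to genotype. That depth sets their bounds, which are not ends of transcripts. Of these, 6 fell in the mutant and 0 rose (edgeR in the model of the genes, adjusted over the 8 regions). The unadjusted p was under 0.05 for 6. Those from 5017 to 5142 and from 5224 to 5324 need not be separate RNAs. Forward-strand RNA continued between them, and at 5162 its scaled depth was 49.29 to 79.97 in the wild type and 12.62 to 26.33 in the mutant. On the forward strand, the RNA from 5017 to 5142, opposite mt-Ta and mt-Tn, went from a normalized depth of 355 ± 146 in the wild type to 121 ± 30.3 in the mutant (SD, n = 3; 2.93-fold lower, log2 -1.55, SE 0.28, edgeR adjusted p = 8.37e-07). The RNA from 5224 to 5324, opposite mt-Tc and mt-Ty, was 2.72-fold lower (log2 -1.45, -1.05 scaled to tRNA; 120 ± 19.4 and 43.9 ± 5.66) and that from 3776 to 3844, opposite mt-Tq, 2.08-fold lower (log2 -1.06, -0.67 scaled to tRNA; 167 ± 42.7 and 80.5 ± 19.3). All 3 are antisense to light-strand tRNAs, with an exact permutation p of 0.1 each, the smallest that 3 against 3 libraries allow. A weaker one, from 15356 to 15423 opposite mt-Tp, had a log2 change of -0.59 (edgeR adjusted p = 0.0448). It lost its call by library totals (0.209) or scaled to tRNA (0.693), and when any library but mutant replicate 3 was left out (0.0699 to 0.411). Its log2 change was -0.46 by totals, -0.18 scaled to tRNA and -0.20 without mutant replicate 1. It was -1.02 without mutant replicate 3, where the call held, and -0.54 to -0.64 without any of the other 4 libraries, whose omission ended the call.

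On the reverse strand, beyond the annotated genes, the RNA from 15610 to 15642 was 3.06-fold lower in the mutant (114 ± 12.6 and 38.1 ± 7.55, SD, n = 3, edgeR adjusted p = 3.93e-07). That from 15923 to 16047 was 1.71-fold lower (236 ± 29.2 and 138 ± 33.0, log2 -0.77, edgeR adjusted p = 0.00716). Scaled to tRNA, the latter measured log2 -0.38 and lost its call (edgeR adjusted p = 0.195). The most abundant of the 8 regions, from 16100 to 16188, did not pass (3500 ± 257 and 2480 ± 818, log2 -0.50, SE 0.28, edgeR adjusted p = 0.0846; log2 -0.12 scaled to tRNA and -0.28 without mutant replicate 1), nor did the one opposite mt-Nd5 from 12924 to 12997 (53.0 ± 3.92 and 43.5 ± 10.7, edgeR adjusted p = 0.291).

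The lower antisense RNA next to mt-Tw may be a scaling effect of mutant libraries rich in rRNA fragments, but scaled to the tRNA genes the region from 5017 to 5142 still differed by -1.17 (SE 0.28, edgeR adjusted p = 0.00151). For a general fall of short mitochondrial RNA, the region was set against the 19 tRNA genes. It lay -1.28 from their median, with an SD of 0.37, so it fell further than they did. That median replaced, after the result was seen, a comparison with the lowest tRNA gene, which gave -0.65. The region was picked for its fall and other RNA outside genes also fell, so a general fall is not excluded. No biological explanation was tested, and the fall was not confined to RNA opposite tRNAs, since the reverse-strand region from 15610 to 15642 differed by -1.61. The region from 5017 to 5142 holds the trailer of mt-Tw and that from 3776 to 3844 most of the trailer of mt-Ti, so the fall of these trailers may reflect the fall of those regions rather than a change in 3′ cutting. Scaled depth per library was 14.29 to 27.77 at 5016, the last base of mt-Tw, and 130.43 to 729.93 at 5017. Most of the trailer depth of mt-Tw thus came from RNA that begins there, which argues against uncut 3′ ends of mt-Tw as its source.

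The rise of mt-Rnr1 fragments could come from mutant replicate 1, the deepest library, but without it the log2 change was 0.70 (SE 0.22, edgeR adjusted p = 0.046). More fragments of all long RNA, as partial RNA breakdown would give, could also raise it: 11 of the 13 protein-coding genes had a log2 change above 0 too. Their median of 0.42 was 0.17 without mutant replicate 1 and -0.28 with rRNA as the scale. The median of the 2 rRNA genes was higher than theirs, at 0.71, and at 0.54 without mutant replicate 1. With rRNA as the scale it was 0.05. A scale shifts all genes of a library alike, so that setting adds no further comparison of the 2 classes. The ranges overlapped, at 0.51 to 0.90 for rRNA and -0.14 to 0.78 for protein-coding genes, and the difference was not tested. All mutant libraries hold a larger rRNA share than all wild-type ones. RNA quality and a genotype effect on that share cannot be separated here, because no measure of RNA quality was used.

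Low depth over position 9 went with a purine there, and stops of reverse transcriptase at a modified purine are a possible source. Position 9 reached 97.0% of the highest depth over bases 20 to 60 in the 3 tRNAs with C9 or U9 and 49.8% in the 10 with A9 or G9 (exact permutation test over tRNAs, p = 0.0175), and the ranges, 94.4% and above against 2.11% to 84.9%, did not overlap. tRNAs are not independent replicates, and other modified bases between positions 9 and 20 were not tested as a source of stops. The share also depends on where RNA fragments begin, which was not tested. An RNA with a stop can be lost from the reads at all of its bases. Stops then lower the share only where other RNA already begins 3′ of position 9, so the share cannot show stops by itself. In the 10 purine tRNAs the mean was 53.0% ± 1.84 in the wild type and 46.5% ± 4.10 in the mutant (SD, n = 3; exact permutation p = 0.1, the smallest possible), and in the 3 others 97.8% ± 0.544 and 96.1% ± 1.69 (exact permutation p = 0.3).

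The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed depth the real split gave 2 genes and the highest of the others 0, so 1 of the 10 splits gave as many. For trailers the real split gave 2 and the highest of the others 0, again 1 of 10. For position 9 mismatch, leaders and other sites the real split and the highest of the others gave 0, so all 10 gave as many.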
